A study of Arabidopsis thaliana with 4 samples.

How the data were processed

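Small RNA of Arabidopsis flowers was sequenced in 4 libraries, 2 of input RNA and 2 of RNA from an HA-AGO1 immunoprecipitate. Per the submitters' processing notes, RNA of 18 to 24 nt was recovered from a polyacrylamide gel, ligated to adaptors, amplified and sequenced on an Illumina instrument. The authors deposited, for each library, a list of mapped small RNA sequences in which the value is the raw read count of a sequence, repeated at each of its places. Per the deposited description of the files and the series' design text, reads were mapped to the TAIR 9 genome with CASHX version 2.1, keeping perfect matches; the files list places on the 5 nuclear chromosomes. The deposited counts are not normalized. The deposited sequences are 18 to 30 nt long.

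The reference used here was the RefSeq annotation of TAIR10.1. Its nuclear chromosome sequences were checked against the files, and 100% of the places in each library matched the reference sequence at the stated coordinates, so positions are given 1-based on these chromosomes. A place was given to the first of these classes that held it whole: MIRNA gene, TAS locus, structural RNA, sequences that also occur in a chloroplast or mitochondrial genome, pseudogene, other gene in sense, other gene in antisense, intergenic. A read was split evenly over its places. The design had named a class and a list of transposable element genes. The annotation marks no such class, and its 3917 nuclear pseudogene loci, of which 29 are described as transposons and 3865 carry no description, were used instead. A list of organelle loci could not be tested because the files list nuclear places only. The annotation holds the 18S and 5.8S rRNA genes but no 25S gene, and reads within 4000 nt downstream of the 2 5.8S genes, counted as intergenic, made up 0.421% and 0.469% of the input libraries and 0.0697% and 0.244% of the IP libraries. In the table of loci a place inside a MIRNA gene, TAS locus or structural RNA counted for that locus alone, elsewhere each overlapping locus received the read, and both strands were summed.

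Some 18-nt sequences carried the same name number as a longer sequence and repeated its count in every case (98, 66, 21 and 24 sequences in input replicates 1 and 2 and IP replicates 1 and 2). They were left out, which removed 0.271% and 0.228% of deposited reads from the input libraries and 3.81% and 3.00% from the IP libraries. In input replicate 1, 5 duplicate lines were also removed. The reads used were 1243056, 874482, 500556 and 1107793, and a count of 0 allows a share of up to 0.000241%, 0.000343%, 0.000599% and 0.000271% (3 reads of the total). Intervals on shares are Wilson intervals at 95%.

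Reads were tested in 4 tables: 32 classes of length and 5' nucleotide, distinct sequences, mature miRNAs of the annotation by exact sequence, and annotated loci (split counts rounded to whole numbers). The test was edgeR (version 4.0.16, R 4.3.3) with glmQLFit and glmQLFTest, group as the only term, the total reads of the library as the offset and no TMM factors, since an immunoprecipitate changes the makeup of a library. Features were filtered with filterByExpr, except for the 32 classes. Calls had a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change was its size divided by the root of the F statistic. Lists of loci were tested with camera (limma 3.58.1) on log2 counts scaled to the library total with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation. Guide against opposite strand, 22- against 21-nt guides and tasiRNAs by 5' nucleotide were tested across miRNAs or sequences by permutation, exactly where few and otherwise with 100000 resamples. miRNAs and sequences are not independent replicates.

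The samples, tests, alternatives, lists and the rule for named genes were fixed before the files were opened. The rule named 14 miRNAs in advance, the 6 largest changes each way among called miRNAs with a mean of 10 RPM or more and no overlap of the groups, the 8 TAS loci, the 6 largest each way among called protein-coding genes with 5 RPM or more and the 3 largest each way among transposable element genes (here pseudogenes) by the same rule, 3 members with the smallest p in each list, and tasiR-ARF. The alternatives were TMM, DESeq2 (1.42.0), the replicate number as a block, other filters, sequences in 1 place, 20 to 22 nt alone, distinct sequences, and each library left out. Chosen after seeing the data were an offset without structural RNA, keeping the 18-nt sequences, leaving out sequences of MIRNA genes, a strand with 0 IP reads at its bound, and a same-arm product kept. A first run had wrongly paired miR447a with a product of its own arm. This pair was removed after its result was known, which changed the permutation p from 0.0155 to 0.0298. Apart from resampling error, each p is the smallest that this test of the median can give for its number of guides.

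The tests were tried on simulated counts drawn from the real means, depths and dispersions, over 20 draws with up to 200 changed features. The means were pooled over both groups. In the real data far more sequences were called (566 higher and 2174 lower of 3765), so recovery there can differ from the values below. The number of draws was set after a first single draw recovered 0 changed sequences and 0 changed miRNAs. For sequences (3765) the edgeR test recovered 1.55% of 4-fold and 26.9% of 16-fold changes, for miRNAs (73) 8.75% and 70.0%, for loci (2763) 26.5% and 89.1%, and for the 32 classes 26.3% and 75.0%. Of unchanged features, 4.40%, 3.90%, 4.56% and 2.88% had an unadjusted p under 0.05 in the same order. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.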

Results

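Small RNA was sequenced from Arabidopsis thaliana flowers that carry ARGONAUTE1 (AGO1), the main miRNA effector protein of plants, fused to an HA epitope tag and driven by the AGO1 promoter. The input group held 2 libraries of small RNA from total RNA, and the HA-AGO1 IP group held 2 libraries of small RNA recovered from an anti-HA immunoprecipitate (IP). The libraries held 1243056 and 874482 mapped reads for input replicates 1 and 2 and 500556 and 1107793 for IP replicates 1 and 2. The numbers of distinct sequences were 388407, 201924, 46324 and 84903 in the same order. The labels do not say that replicates came from separate plants, so p-values measure only the spread between these libraries, which may be technical. A permutation of 2 libraries against 2 cannot give a two-sided p below 0.333, so the share comparisons carry no test of their own. Intervals and floors cover counting error only, because amplified reads are not independent molecules. Where a library is left out, 1 group holds 1 library and the spread comes from the other group alone. Calls lost or kept in those settings therefore do not measure how firm a call is.

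The first comparison asked which sizes and 5' nucleotides the AGO1-bound fraction held relative to input. Reads of 21 nt, the length of most plant miRNAs, made up 78.5% ± 8.21 (SD, n = 2) of the IP libraries and 13.1% ± 3.18 (SD, n = 2) of the input libraries. Reads of 24 nt, the usual length of siRNAs from repeats and transposons, made up 5.75% ± 2.95 (SD, n = 2) of the IP and 31.8% ± 16.7 (SD, n = 2) of the input. The single input libraries stood far apart here, at 43.6% (Wilson 95% interval 43.5 to 43.7) and 19.95% (19.87 to 20.04). A 5' U, the known preference of AGO1, was present on 94.9% ± 1.52 (SD, n = 2) of IP reads and on 22.1% ± 7.89 (SD, n = 2) of input reads. In each of these shares both IP libraries lay beyond both input libraries, an arrangement that chance gives in 33.3% of cases with 2 against 2. With each distinct sequence counted once the difference of 21 nt was 18.1 percentage points instead of 65.5, and that of 24 nt lay between -37.9 and -14.2 with a library left out, against -26.0.

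The 5' U was also more frequent in both IP libraries within each length from 20 to 24 nt. Among 21-nt reads it was on 97.2% ± 0.461 in the IP and 62.1% ± 2.56 in the input (SD, n = 2 each). Among 22-nt reads the shares were 87.9% ± 1.48 and 37.1% ± 0.826, and among 24-nt reads they were 92.9% ± 0.0370 and 20.95% ± 0.350 (SD, n = 2 each). Input 24-nt reads mostly began with A, at 57.5% ± 0.163, against 3.97% ± 0.570 in the IP (SD, n = 2 each).

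Over 32 classes of length and 5' nucleotide, the test of edgeR (quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05) called 3 higher and 19 lower in the IP. The 3 classes that rose were reads with 5' U of 20 nt (log2 fold change 2.02 ± 0.75 SE, adjusted p = 0.0161), 21 nt (3.23 ± 0.94 SE, adjusted p = 0.00348) and 22 nt (1.66 ± 0.74 SE, adjusted p = 0.0434). In the main edgeR test reads of 24 nt with 5' A showed the largest fall, -6.38 ± 0.94 SE on the log2 scale (adjusted p = 1.49e-07). It was followed by 19-nt reads with 5' G (-6.02 ± 0.97 SE, adjusted p = 4.76e-07), at -5.24 without IP replicate 1. This order depended on the settings. The 19-nt reads with 5' G fell further with TMM (-4.05 against -3.90), DESeq2 (-3.87 against -3.82) and the offset without structural RNA (-6.96 against -6.95). They also fell further without input replicate 1 (-6.68 against -5.70) and without IP replicate 2 (-7.89 against -6.84). The 24-nt reads with 5' U were at -0.32 ± 0.73 SE and did not pass (adjusted p = 0.677), but they passed as higher with TMM (2.103, edgeR adjusted p = 0.000138) and DESeq2 (2.18, adjusted p = 0.000126). With 1 library left out the log2 fold change of reads with 5' U ran from 2.97 to 3.55 for 21 nt. It ran from 1.37 to 1.97 for 22 nt and from 1.54 to 2.38 for 20 nt. The rises of 20 and 22 nt were lost with the offset without structural RNA, chosen after seeing the data (edgeR adjusted p = 0.0597 and 0.0822). With TMM scaling the split was 8 higher and 7 lower, with DESeq2 9 and 9, and leaving out input replicate 1 or input replicate 2 gave 1 and 7 each time.

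**Figure D1:**
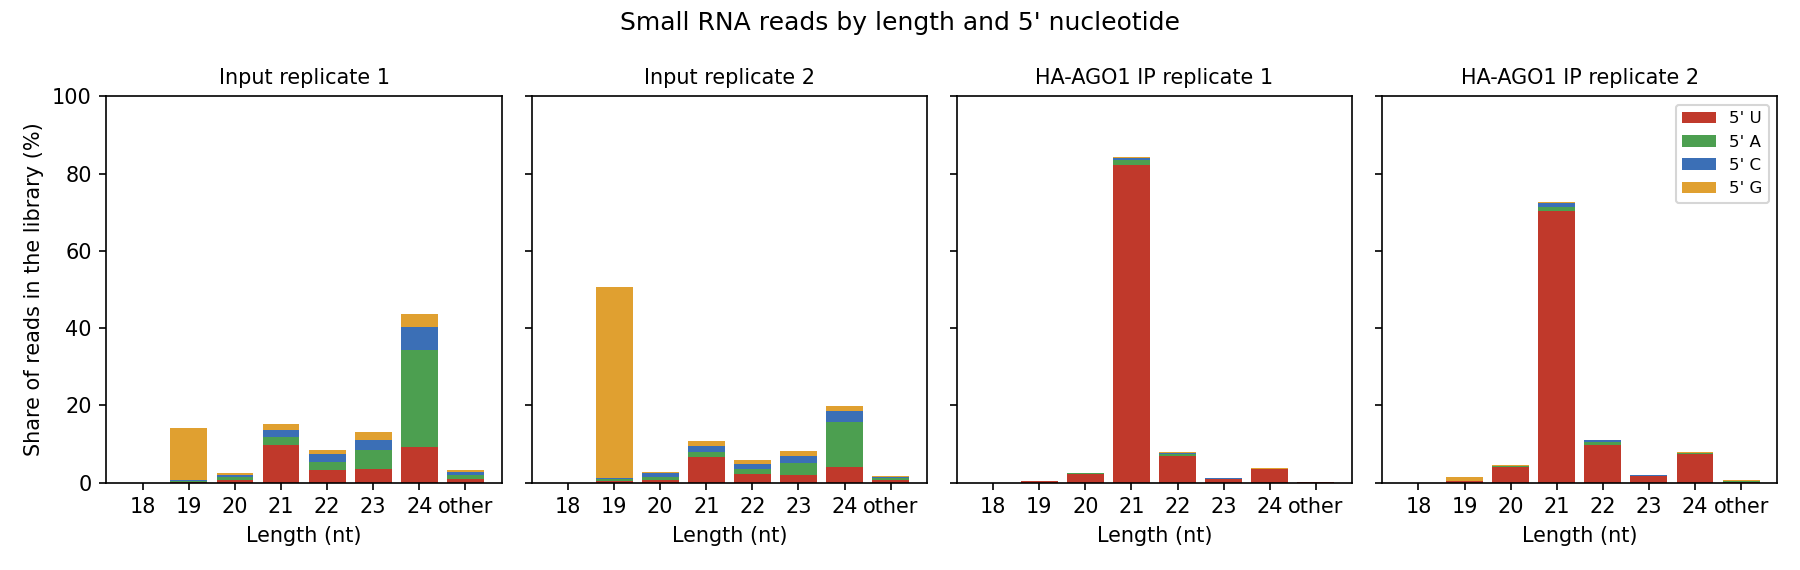
Share of reads (y axis, % of the library) by length in nt (x axis, lengths beyond 24 nt pooled as other) for each of the 4 libraries, with the colours of the stacked bars giving the 5' nucleotide. In both IP libraries the 21-nt reads with 5' U form the tallest bar, while the 19-nt reads with 5' G and the 24-nt reads with 5' A seen in the input libraries are nearly missing.

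The second comparison asked which kinds of RNA the reads came from. MIRNA genes gave 74.9% ± 6.27 of IP reads and 8.04% ± 2.51 of input reads (SD, n = 2 each). TAS loci, the sources of trans-acting siRNAs (tasiRNAs), gave 1.12% ± 0.0372 in the IP and 0.627% ± 0.110 in the input (SD, n = 2 each), a difference of 0.495 percentage points that was 0.053 with sequences in 1 place. Within 21-nt reads the share of TAS loci was lower in the IP, at 1.12% ± 0.0200 against 3.68% ± 0.373 (SD, n = 2 each). Structural RNA (rRNA, tRNA, snRNA and snoRNA) took 1.19% ± 0.982 of the IP and 35.4% ± 25.4 of the input (SD, n = 2 each). The input replicates differed strongly in that class, with tRNA at 14.8% of input replicate 1 and 50.4% of input replicate 2. A single 19-nt sequence that matches 6 tRNA genes, GACCGCAUAGCGCAGUGGA, made up 8.08% and 34.0% of these libraries and 0.0801% and 0.544% of the IP libraries. Annotated pseudogenes gave 2.26% ± 0.593 of IP reads and 5.80% ± 2.51 of input reads (SD, n = 2 each). Intergenic places gave 13.0% ± 2.79 and 34.5% ± 15.5, other genes in sense 4.76% ± 1.53 and 10.2% ± 2.75, and in antisense 2.66% ± 0.388 and 4.80% ± 2.08 (SD, n = 2 each). Sequences that also match an organelle genome were at 0.0600% ± 0.0321 and 0.641% ± 0.0986 (SD, n = 2 each). With each distinct sequence counted once, the difference of MIRNA genes was 0.578 percentage points instead of 66.9 and that of intergenic places -1.17 instead of -21.5, while the structural and antisense differences changed sign, to 0.213 and 1.65 points higher in the IP. With a library left out the difference ran from -52.2 to -16.3 for structural RNA, -32.5 to -10.5 for intergenic places, -5.31 to -1.76 for pseudogenes, -7.40 to -3.52 for sense and -3.61 to -0.663 for antisense.

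**Figure D2:**
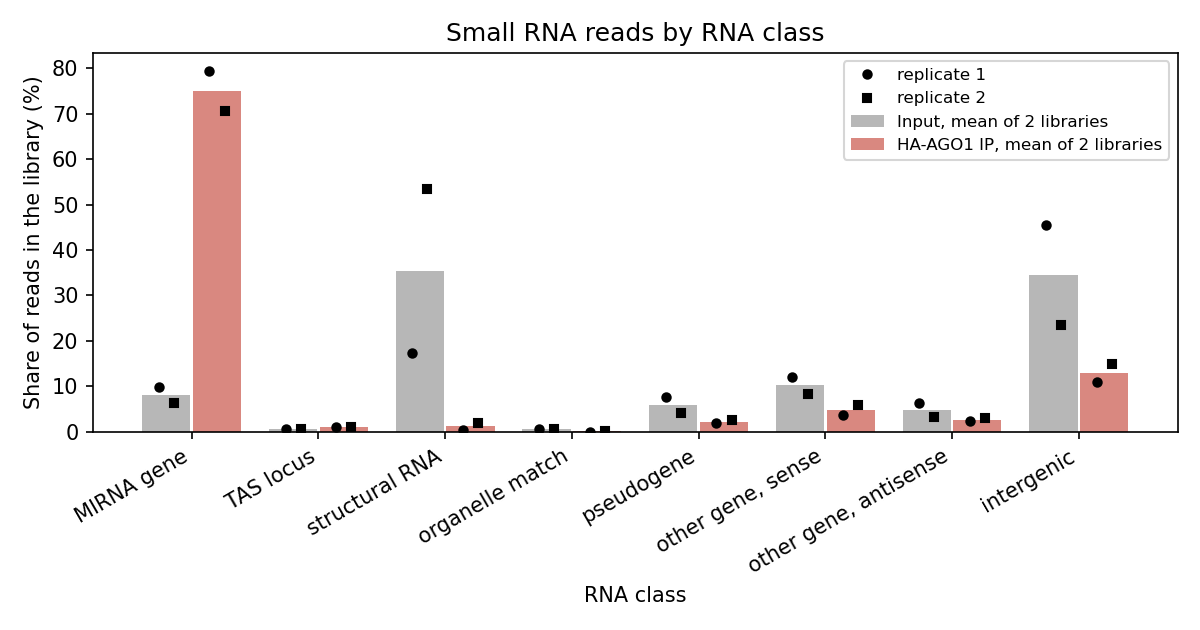
Share of reads (y axis, % of the library) by RNA class (x axis), with bars for the mean of 2 libraries per group and symbols for the single replicates. MIRNA genes stand at 74.9% in the IP and 8.04% in the input, and the 2 input replicates lie far apart for structural RNA and intergenic reads.

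The third comparison took single sequences. Of 3765 sequences that passed the expression filter, edgeR's quasi-likelihood test called 566 higher and 2174 lower in the IP at an adjusted p under 0.05. Of the 566 that rose, 539 began with U. By length, 211 of 636 sequences of 21 nt and 260 of 650 of 22 nt rose, against 57 of 1746 of 24 nt, of which 1384 fell. Of 384 sequences of structural RNA, 271 fell and 7 rose. Without input replicate 1 or without input replicate 2, edgeR called 0 sequences in either direction, with 845 and 1973 at an unadjusted p under 0.05; DESeq2 on all 4 libraries called 388 higher and 2283 lower.

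The fourth comparison asked which mature miRNAs the IP over- or under-represented. Of 73 mature miRNAs tested, 27 were higher and 9 lower in the IP (edgeR quasi-likelihood, adjusted p under 0.05). Of the 55 with 5' U, 26 rose and 1 fell. Of the 8 with 5' C, 0 rose and 5 fell by the same edgeR test. All 5 that fell were strands opposite a guide. The guides with 5' C, miR845a (2.21), miR395a (1.90) and miR169a (0.89 on the log2 scale), lay above 0 without passing. These counts therefore do not separate the 5' nucleotide from the strand.

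The most abundant miRNA was miR159a, a regulator of GAMYB-like transcription factors (chromosome 1, 27713234 to 27713254, in the MIRNA gene AT1G73687). It made up 54.7% and 38.1% of IP replicates 1 and 2, at 463946 ± 116902 RPM (reads scaled to the library total) against 43132 ± 14563 in the input (SD, n = 2 each; log2 fold change 3.43 ± 0.78 SE, edgeR adjusted p = 0.00028). The largest rise was that of miR161.1, which targets pentatricopeptide repeat (PPR) transcripts, from 59.98 ± 15.3 to 11722 ± 685 RPM (SD, n = 2 each; 7.61 ± 1.33 SE, edgeR adjusted p = 4.38e-06). Next came miR170 and miR171a, which target HAIRY MERISTEM (HAM) transcription factors, at 5.49 ± 1.12 SE and 5.01 ± 1.22 SE. The input held few reads of miR170, with 5 in replicate 1 and 1 in replicate 2. The rise of miR779.2 was 4.75 ± 1.17 SE and of miR159c 4.49 ± 1.14 SE. The latter had 6 reads in input replicate 1 and 0 in input replicate 2. Its rise was 3.65 without input replicate 2, and no finite value can be given without input replicate 1. The sequence differs by 1 nt from miR159b, which had 14420 input and 215750 IP reads and rose by 4.29 ± 0.93 SE. Whether misread copies of miR159b gave the reads of miR159c was not tested. miR165a, a regulator of class III HD-ZIP factors, rose by 4.39 ± 1.21 SE on the log2 scale. Among miRNAs named in advance, miR398b (4.16 ± 1.03 SE), miR166a (3.08 ± 1.08 SE, adjusted p = 0.0148) and miR168a, which targets AGO1 itself (2.43 ± 0.96 SE, adjusted p = 0.0276), also rose by the edgeR test.

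Among called miRNAs with a mean of 10 RPM or more over the 4 libraries, the 6 strongest falls included 5 strands that lie opposite a guide. The 3' arm of MIR390b held 229 reads in the input libraries and 1 in the IP libraries, a ratio of 0.00575 (95% exact counting interval 0.000145 to 0.0324). The passenger of miR390a fell by 3.76 ± 1.08 SE on the log2 scale, from 402 ± 46.6 to 30.3 ± 24.97 RPM (SD, n = 2 each; edgeR adjusted p = 0.00385). The 3' strand of MIR824 fell by 3.41 ± 1.14 SE, that of MIR393b by 3.38 ± 1.09 SE and the passenger of miR396b by 2.93 ± 0.99 SE. The other was the guide miR2111a, which fell by 3.28 ± 1.28 SE (edgeR adjusted p = 0.0254). Its call was lost without IP replicate 1 (-2.61, edgeR adjusted p = 0.0794), without either input library and with no filter (edgeR adjusted p = 0.0939), and IP replicate 1 held 0 of its reads against 5 in IP replicate 2. With no filter the named strands of MIR393b and MIR396b also missed the threshold (edgeR adjusted p = 0.0624 and 0.0794). Below that mean, and singled out after its values were seen, miR172b-5p had 35 input and 0 IP reads and was at least 8.86-fold lower (edgeR adjusted p = 0.0125). Not all opposite strands fell. Of 7 tested strands listed as passengers, 4 were called lower and 2 higher. The latter were the passengers of miR403 (3.57 ± 1.03 SE, edgeR adjusted p = 0.00392) and miR408 (2.85 ± 1.19 SE, edgeR adjusted p = 0.0374).

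The 4 tested guides with 5' A did not pass the test with all libraries and the library size as offset. The guide miR390a, known to act with AGO7, stood at 195 ± 111 RPM in the input and 48.0 ± 22.7 RPM in the IP (SD, n = 2 each; -2.01 ± 0.94 SE, edgeR adjusted p = 0.065). miR172a stood at 732 ± 183 and 2615 ± 1088 RPM (1.84 ± 1.08 SE, edgeR adjusted p = 0.131), and miR408 at 357 ± 3.61 and 583 ± 404 RPM (0.71 ± 1.03 SE, edgeR adjusted p = 0.551; SD, n = 2 each). These results depended on the settings. miR390a passed as lower with TMM (-3.52, edgeR adjusted p = 0.0325), DESeq2 (-3.70, adjusted p = 4.93e-05), ends within 2 nt (-2.21, edgeR adjusted p = 0.0387) and the offset without structural RNA, chosen after seeing the data (-2.56, edgeR adjusted p = 0.0137). Its log2 fold change was -1.61 without IP replicate 1 and -2.61 without IP replicate 2. miR172a was at 1.33 without IP replicate 1 and at 2.21 without IP replicate 2, and miR408 at 1.28 without IP replicate 1. With 1 IP library left the spread comes from the input libraries alone. Their SD over miRNAs was 0.424 against 1.23 for the IP libraries (log2 scale), so no test is given for these settings. Among guides with 5' U that were named in advance, miR403 with 2.22 ± 1.23 SE (edgeR adjusted p = 0.114) did not pass, nor did the 24-nt miR163 at 0.86 ± 1.05 SE (edgeR adjusted p = 0.493). Without IP replicate 1 miR403 was at 2.61 and miR163 at 1.65, while miR163 was at -1.02 without IP replicate 2. miR156a, miR173, miR393a, miR472 and miR828 were too scarce for the filter. miR173, the trigger of TAS1 and TAS2 siRNAs, had 2 reads in the input libraries and 0 in the IP libraries.

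The scale of the change depended on the offset, since the median log2 fold change of the 73 miRNAs was 1.84 with library size and 0.26 with TMM. TMM called 7 higher and 10 lower, and DESeq2 9 and 12. Of the rises named above, miR166a (1.501, adjusted p = 0.254), miR168a (0.78, adjusted p = 0.414), miR159c (3.03, adjusted p = 0.143) and miR165a (2.82, adjusted p = 0.0858) missed the threshold with TMM. With DESeq2 miR166a (adjusted p = 0.22), miR168a (adjusted p = 0.543) and miR159a (1.77, adjusted p = 0.0661) missed it, as did miR168a by edgeR with no filter (adjusted p = 0.0806) and miR159a without IP replicate 1 (adjusted p = 0.128). Without input replicate 1 edgeR called 0 higher and 1 lower (9 at an unadjusted p under 0.05), and without input replicate 2 it called 0 in either direction (12 at an unadjusted p under 0.05).

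**Figure D3:**
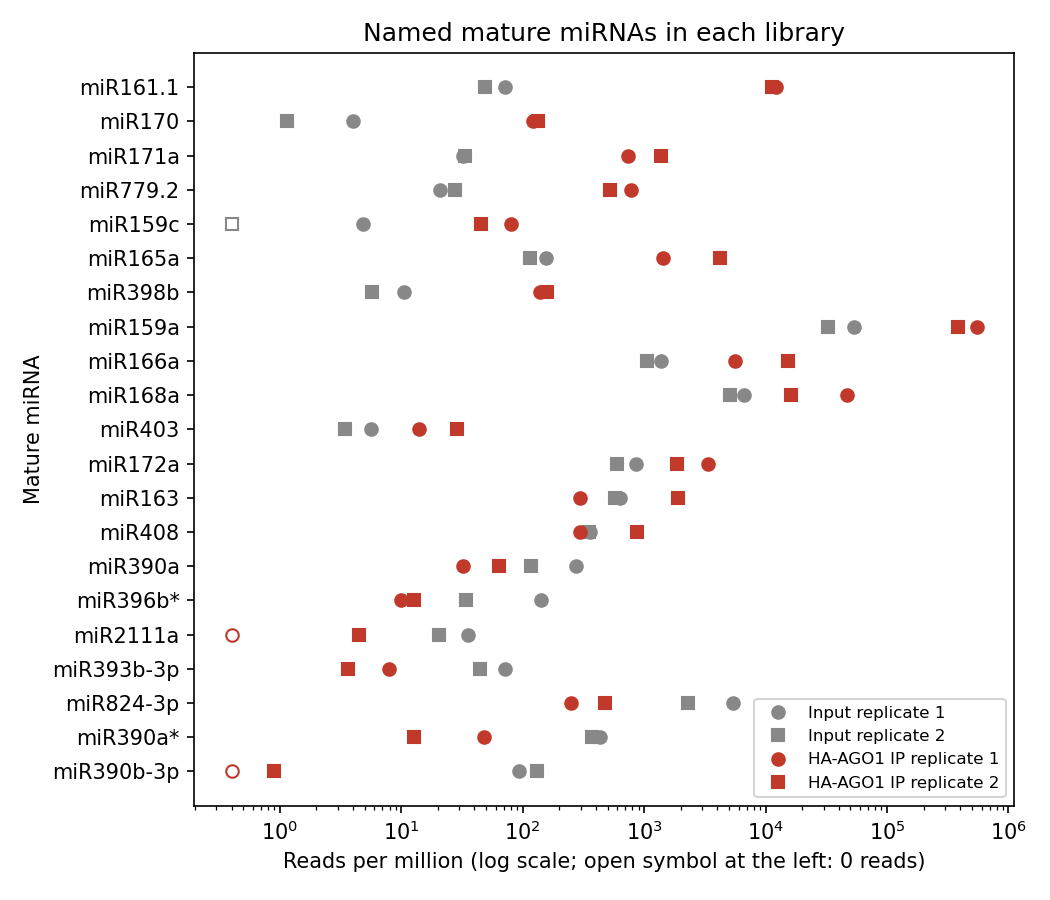
RPM on a log axis (x axis) for the named mature miRNAs that passed the filter (y axis, ordered by log2 fold change), with 1 symbol per library and open symbols at the left edge for 0 reads. miR161.1 lies between 11238 and 12206 RPM in the IP libraries and between 49.2 and 70.8 RPM in the input libraries.

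Both strands of a miRNA duplex were then compared within hairpins. Across 11 guides, the log2 fold change of the guide exceeded that of the opposite strand by a median of 3.53. Of the 11 differences 9 were above 0 (permutation of signs, two-sided p = 0.0298). Apart from resampling error, this p is the smallest that the test of the median can give for 11 guides. It would be no smaller with all 11 differences above 0. The difference was 5.15 for miR168a, 4.78 for miR170 and 4.31 for miR171a, of which the last 2 share 1 opposite strand. For miR172a, whose opposite strand had 0 IP reads, it was at least 4.98, and the median was the same with that guide at its bound. It was -1.35 for miR403 and -2.14 for miR408. Both strands began with the same nucleotide for miR403, miR408, miR170 and miR171a, and with different ones for the other guides. Across the 11 guides strand and 5' nucleotide were therefore not separated. Among the 8 guides left with 50 or more reads per strand all 8 differences were above 0, with a median of 3.85. The exact permutation gave a two-sided p = 0.0625, the smallest that this test of the median can give for 8 guides. Without IP replicate 2 the median was 3.73, with 11 of 13 differences above 0.

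Guides of 22 nt, the length known to trigger secondary siRNAs, were set against guides of 21 nt. The 4 of 22 nt (miR167d, miR447a, miR771 and miR848) had a median log2 fold change of 2.63 and the 36 of 21 nt a median of 2.096. The difference of 0.53 was not separable from chance (permutation, two-sided p = 0.598). The 22-nt guides miR173, miR393a, miR472 and miR828 were too scarce for the filter, so the comparison does not cover them. 

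Among 21-nt sequences of the TAS loci, the 5' nucleotide went with the change in the IP. The 57 sequences with 5' U had a median log2 fold change of 1.14, and 42 of them were above 0. The 22 sequences with another 5' nucleotide had a median of -0.67, with 9 above 0, and the medians differed by 1.82 (permutation, two-sided p = 0.00335). By the edgeR sequence test 13 of the 57 rose, and 0 passed without either input library. The medians differed by 4.44 without IP replicate 1 and 2.38 without IP replicate 2, and by 1.81 and 2.46 without input replicates 1 and 2. tasiR-ARF, the TAS3 siRNA that targets auxin response factors, is known in several forms. The form UUCUUGACCUUGUAAGGCCUU was at 382 ± 84.6 RPM in the input and 74.1 ± 76.5 RPM in the IP (SD, n = 2 each; -2.35 ± 1.18 SE, edgeR adjusted p = 0.062). The form UUCUUGACCUUGUAAGACCCC was at 18.6 ± 2.09 and 29.4 ± 27.4 RPM (SD, n = 2 each; 0.69 ± 1.23 SE, edgeR adjusted p = 0.62).

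The last comparison summed reads over annotated loci. Of 2763 loci tested, 59 were higher and 1172 lower in the IP (edgeR quasi-likelihood, adjusted p under 0.05). MIRNA genes accounted for 48 of the 59, with 15 of 114 lower. Of 270 structural RNA loci, 254 fell and 0 rose, and of 1168 pseudogenes 324 fell and 0 rose. Of 1204 other genes, 11 rose and 579 fell. The split moved to 213 higher and 291 lower with TMM, which shifted the median of all loci by 1.49, and to 138 and 118 with DESeq2. Leaving out IP replicate 1 gave 11 and 13, IP replicate 2 gave 6 and 14, and input replicate 1 gave 20 and 240. Without input replicate 2 there were 19 higher and 1163 lower.

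The largest rises among protein-coding genes were those of HAM3 (AT4G00150), HAM2 (AT3G60630) and HAM1 (AT2G45160), at 4.73 ± 0.88, 4.53 ± 0.86 and 4.42 ± 0.86 SE on the log2 scale. They are targets of miR171, and 97.3%, 99.9% and 98.5% of their IP reads were sequences that also map inside a MIRNA gene. Only 2.52%, 0.987% and 1.94% of their reads lay on the sense strand. A single read of such a sequence cannot be assigned to 1 source. The IP counts of the 3 genes were nearly equal, at 93.3 to 95.3 in IP replicate 1 and 388 to 399 in IP replicate 2. miR171a had 367 and 1532 reads there. These values argue that the 3 rises mostly hold the same miRNA reads, split over several places, and are not separate results. Without IP replicate 2 all 3 missed the threshold (edgeR adjusted p = 0.15). With all sequences of MIRNA genes left out, an alternative chosen after seeing the data, 8 loci were higher and 1163 lower.

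RK3 (AT4G21380), a receptor-like kinase, rose from 4.23 ± 2.74 to 44.1 ± 1.10 RPM (SD, n = 2 each; 3.26 ± 0.97 SE, edgeR adjusted p = 0.00369). TCP3 (AT1G53230), a transcription factor targeted by miR319, rose from 2.62 ± 2.001 to 21.2 ± 3.87 RPM (SD, n = 2 each; 2.84 ± 0.87 SE, edgeR adjusted p = 0.00505), and it overlaps the gene AT1G53233. AT5G37793 rose by 2.29 ± 0.95 SE (edgeR adjusted p = 0.0374). Without IP replicate 1 the edgeR adjusted p of RK3, TCP3 and AT5G37793 was 0.102, 0.193 and 0.188, and without IP replicate 2 it was 0.15, 0.208 and 0.267. Among the falls, AT5G55570 (chromosome 5, 22514214 to 22515458), PEN3 (AT5G36150), SAHH2 (AT3G23810), TSM1 (AT1G67990), BGLU29 (AT2G44470) and AAC1 (AT3G08580) had 0 reads in both IP libraries. Against a floor of 3 reads over the IP group they were at least 52.5-fold, 25.7-fold, 19.6-fold, 13.8-fold, 13.4-fold and 12.4-fold lower. Their calls were lost without IP replicate 1 (edgeR adjusted p = 0.0759 for AT5G55570 and 0.0841 for the others) and without IP replicate 2 (0.15 for each). Reads of SAHH2 and AAC1 were 100% sense with a commonest length of 19 and 20 nt, while the commonest length at AT5G55570, PEN3, TSM1 and BGLU29 was 24 nt. The pseudogenes AT1G57710, AT3G22955 and AT3G25450 also had 0 IP reads and were at least 24.8-fold, 13.2-fold and 9.87-fold lower.

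Lists of loci fixed in advance were tested with camera against the remaining loci. The median edgeR log2 fold change of all tested loci was -1.72. With reads of 20 to 22 nt alone it was 0.55 over 938 loci. Camera was not run on those reads, so its results do not separate a list from the lengths of its reads. Each set call was lost when the correlation between loci was estimated. With 4 libraries that test has few residual degrees of freedom and could hardly keep any call. Its result therefore does not count against a set. The estimated correlations ran from 0.122 (TAS) to 0.901 (NBS-LRR), above the preset 0.01, so the preset calls are not secure either. Of the 8 TAS loci 7 were tested and 0 passed by edgeR, by themselves or adjusted over the list alone, although the set stood above other loci (camera adjusted p = 2.59e-06; adjusted p = 0.17 with an estimated correlation). Their values ran from 0.23 ± 0.90 SE for TAS1C to 1.43 ± 0.88 SE for TAS1A, with TAS1B at 1.21 ± 0.88 SE, TAS2 at 0.89 ± 1.13 SE, TAS3 at 0.60 ± 0.93 SE, TAS3b at 0.81 ± 0.81 SE and TASIR-ARF (AT5G57735) at 1.16 ± 0.73 SE. TAS2 was at 3078 ± 714 RPM in the input and 5703 ± 220 RPM in the IP (SD, n = 2 each). With DESeq2 TAS1A (2.97, adjusted p = 5.41e-05), TAS1B (2.79, adjusted p = 0.00101), TAS2 (2.37, adjusted p = 0.00104), TAS3b (2.28, adjusted p = 0.00355) and TASIR-ARF (2.48, adjusted p = 0.0032) passed, and with TMM these except TAS2. With the offset without structural RNA, chosen after seeing the data, their values were smaller: TAS1A 0.79, TAS1B 0.56, TASIR-ARF 0.45, TAS2 0.23 and TAS3b 0.13, with TAS3 at -0.16, TAS1C at -0.44 and 0 passing (smallest edgeR adjusted p = 0.158). TAS4 (AT3G25795) had 2 input and 4 IP reads and was not tested.

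Of the 13 PPR transcripts tested, 1 rose and 0 fell, and 0 passed when adjusted over the list alone (camera adjusted p = 6.73e-11; adjusted p = 0.202 with an estimated correlation). The member that rose was AT1G62914, at 1.72 ± 0.75 SE (edgeR adjusted p = 0.0488), while AT1G63080 was at 1.46 ± 0.77 SE and AT1G63400 at 1.39 ± 0.74 SE. Reads of these transcripts were split over several places, and the call of AT1G62914 was lost without any 1 of the 4 libraries (edgeR adjusted p from 0.164 to 0.574). The auxin receptors AFB2 and AFB3 were at 1.52 ± 0.92 SE and 1.22 ± 0.90 SE, with 0 of 2 passing edgeR (camera adjusted p = 0.00365; adjusted p = 0.202 with an estimated correlation). The NBS-LRR genes AT5G38850 and AT5G43740 were at 1.54 ± 0.79 SE and 0.59 ± 0.76 SE, again with 0 of 2 passing (camera adjusted p = 0.00563; adjusted p = 0.202 with an estimated correlation).

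Of the targets of 21-nt miRNAs 4 were tested and all 4 rose, also when adjusted over the list alone (camera adjusted p = 1.3e-15; adjusted p = 0.132 with an estimated correlation). They were TCP3 and the 3 HAM genes. As stated above, reads of the HAM genes are shared with MIRNA genes and mostly with each other. The 4 rises and the camera result therefore do not rest on 4 separate members. ARF4 and AGO1 were the only members of their lists tested, at 1.35 ± 0.72 SE and 0.38 ± 0.91 SE, and of the 6 MYB genes 0 were tested. Of 114 MIRNA genes 48 rose and 15 fell, or 51 and 15 adjusted over the list alone (camera adjusted p = 4.03e-54; adjusted p = 0.132 with an estimated correlation). Among them MIR159c rose by 4.92 ± 0.95 SE, with the limit given above for miR159c, and MIR829 had 0 IP reads and was at least 8.10-fold lower. Structural RNA fell in 254 of 270 loci, or 260 adjusted over the list alone (camera adjusted p = 1.45e-35; adjusted p = 0.202 with an estimated correlation), including the tRNA gene AT5G35605 at -7.74 ± 1.23 SE and the snoRNA gene AT5G02325, at least 51.1-fold lower. Pseudogenes had a median of -1.43, with 324 of 1168 lower (221 adjusted over the list alone). Camera placed them above the remaining loci (adjusted p = 0.0145), opposite in sign to their median, and adjusted p = 0.761 with an estimated correlation.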

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

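Signals outside the comparisons appeared in the 18-nt sequences that share a name number with a longer sequence, which were left out of the report. They carried 3.81% of the deposited reads of IP replicate 1 and 3.003% of IP replicate 2, above the 0.271% and 0.228% in the input libraries. In all 21 and 24 cases in the IP libraries the 18-nt count equalled that of the longer sequence with the same number.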

How the results depend on the processing

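Most alternatives were chosen before the data were examined, while the offset without structural RNA, the 18-nt sequences kept, the sequences of MIRNA genes left out and both added settings for opposite strands were chosen after seeing the data. The cause of a change was not tested unless stated. No named miRNA or locus that passed the test changed direction under any alternative, while miR163, miR408, TAS1C, TAS3 and AGO1, which did not pass, changed sign under some, as did 24-nt reads with 5' U with TMM (2.103) and DESeq2 (2.18). Counts of calls are given as higher and lower in the IP. With a library left out, 1 group holds 1 library and the spread comes from the other group alone. Those counts therefore do not measure how firm the calls are. Size classes (3 and 19) gave 8 and 7 with TMM, 9 and 9 with DESeq2, 1 higher with the replicate block, 1 higher with the offset without structural RNA, and 0 to 2 and 7 to 20 with a library left out. Sequences (566 and 2174) gave 128 and 1007 with the block, 3265 lower with the offset without structural RNA, 1316 and 6240 with a minimum of 10 reads, which tests more sequences, and 0 to 923 and 0 to 3149 with a library left out. miRNAs (27 and 9) gave 7 higher with TMM, 9 higher with DESeq2, 12 and 3 with the block, 17 and 5 with no filter, and 0 to 40 and 0 to 15 with a library left out. Loci (59 and 1172) gave 213 and 291 with TMM, 138 and 118 with DESeq2, 12 and 220 with the block, 2867 lower with the offset without structural RNA, 26 and 712 with no filter, 34 and 590 with sequences in 1 place, 116 and 162 with 20 to 22 nt alone, 8 higher without sequences of MIRNA genes, and 6 to 20 and 13 to 1163 with a library left out.

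The replicate numbers were not taken as pairs: there are only 2, and deviations of same-numbered libraries correlated at -0.10 (classes), 0.07 (sequences), 0.11 (miRNAs) and 0.07 (loci). Of 2763 loci, 12 nevertheless differed over 4-fold the same way in both groups, among them AGO1 (6.45 and 5.39). Shared material between same-numbered libraries is therefore not excluded. All calls of lists were lost with an estimated correlation, a test that could hardly keep a call with 4 libraries. The camera adjusted p was 0.17 for TAS and 0.202 for PPR, AFB, NBS-LRR and structural RNA. It was 0.132 for targets of 21-nt miRNAs and MIRNA genes and 0.761 for pseudogenes. NBS-LRR lay between 0.00095 and 0.0518 with a library left out. Pseudogenes changed direction with the offset without structural RNA (0.389) and without input replicate 2 (0.128), and lay between 0.00792 and 0.894 with a library left out. Guide against opposite strand kept its sign, with a median of 3.85 at 50 or more reads. The exact permutation p = 0.0625 is the smallest that this test can give for the 8 guides left there. The median was 2.94 to 4.22 with a library left out. A product of the guide's own arm, kept in a first run, gave 3.52 over 12 guides (permutation p = 0.0155). Apart from resampling error, that p is also the smallest for 12 guides.

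Share differences, IP minus input in percentage points, moved as follows. With distinct sequences 21 nt went from 65.5 to 18.1, 5' U from 72.8 to 54.7, MIRNA genes from 66.9 to 0.578, TAS loci from 0.495 to 0.626, structural RNA from -34.2 to 0.213, pseudogenes from -3.54 to -0.502, other genes in sense from -5.46 to -0.908 and antisense from -2.14 to 1.65, and intergenic from -21.5 to -1.17. With sequences in 1 place 24 nt went from -26.0 to -43.1, and the others to 63.9 (5' U), 0.053 (TAS), -2.48 (structural), -1.19 (organelle), -10.2 (sense), -5.50 (antisense) and -41.1 (intergenic). Without structural RNA and organelles 5' U went to 62.8. IP replicate 1, with 500556 reads, has the coarsest floor.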

Other observations

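The tests of the tRNA shares, of carry-over and library-wide loss among 24-nt reads and of the 3' end as the whole cause were set up after the values they use had been seen.

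At pseudogenes, intergenic places and other genes the lengths of the reads differed between IP and input. Reads of 22 nt made up 42.4% ± 3.12 of pseudogene reads in the IP and 12.0% ± 1.32 in the input, and reads of 24 nt 22.2% ± 5.57 and 58.1% ± 6.55 (SD, n = 2 each). For intergenic reads the 22-nt share was 32.4% ± 4.09 in the IP and 9.14% ± 1.31 in the input, and for antisense reads of other genes 38.7% ± 3.17 and 14.4% ± 1.45 (SD, n = 2 each). Structural RNA differed from these in its 24-nt share, which was 4.96% ± 1.04 in the IP and 1.78% ± 1.40 in the input (SD, n = 2 each). Of the 24-nt reads, 67.5% ± 2.66 were intergenic in the IP and 66.0% ± 1.27 in the input, 9.05% ± 0.166 and 10.8% ± 0.0777 lay in pseudogenes, 1.77% ± 1.16 and 0.361% ± 0.0951 in MIRNA genes, and 0.966% ± 0.565 and 1.61% ± 0.716 in structural RNA (SD, n = 2 each).

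Small RNA from the AGO1 locus itself, the gene carried by the transgene, differed between replicates in both groups. It was at 1578 and 245 RPM in input replicates 1 and 2 and at 2006 and 372 RPM in IP replicates 1 and 2, a ratio of 6.45 and 5.39. Of 2763 loci, 12 differed over 4-fold the same way in both groups, and 6 of these were the tRNA genes of the abundant 19-nt fragment. The locus was singled out after its values were seen, and no explanation was tested.

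The 24-nt reads of the IP mostly began with U, and this pattern was weighed against 3 technical explanations. Unbound input RNA carried through the precipitation would keep the input's 5' nucleotides, but the lowest IP share of 5' U lay 71.7 percentage points above the highest input share. A few abundant sequences do not account for it, because with each distinct 24-nt sequence counted once the share was 91.9% and 91.5% in the IP libraries against 25.7% and 24.1% in the input. A loss of all reads without 5' U during library preparation would lower 5' A miRNAs as much as 24-nt 5' A reads (-6.38 on the log2 scale), but the median of 6 such miRNAs was 1.27 (95% bootstrap interval -2.69 to 2.36). That AGO1 holds a subset of 24-nt RNA chosen by its 5' U stays a hypothesis that was not tested.

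Levels of miRNAs differed more between the IP libraries than between the input libraries, with an SD of the log2 ratio between replicates of 1.84 against 0.768 over 73 miRNAs. Examples are miR319a at 3063 and 28334 RPM and miR167a at 33421 and 5318 RPM in IP replicates 1 and 2. The 52 miRNAs that do not end in A were shifted toward IP replicate 2 by a median of 1.93 relative to the 21 that do (permutation p = 0.00019). This split was not among the tests fixed in advance. Isoforms of 1 miRNA that differ by 1 nt at the 3' end showed a median shift of 1.41 the same way (95% bootstrap interval 0.771 to 1.92, 14 of 19 pairs above 0, permutation p = 0.0112, pairs not independent), so a 3' end bias in library preparation may contribute. Some miRNAs, among them miR159a, miR168a and miR167a, entered both the contrast across miRNAs and the isoform pairs. In the pair of miR159a with its 20-nt isoform (1.92) the latter also maps inside MIR159b. A bias between 3' A and other 3' ends is not the whole cause, since the SD was still 1.62 with the medians of both groups removed. Differences among the other 3' ends were not removed, so a wider 3' end bias stays open. GC content is argued against by a Spearman rho of 0.0355 across miRNAs (95% bootstrap interval -0.205 to 0.277). The design names no difference between replicates, so no biological explanation was tested.

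tRNA fragments took 50.4% of input replicate 2 and 14.8% of input replicate 1. A cut of the gel toward shorter RNA would raise other 19-nt reads alike, but relative to reads outside structural RNA the 19-nt structural reads rose 6.64-fold and the other 19-nt reads 2.14-fold, a ratio of 3.10. General RNA breakdown would raise rRNA alike, but tRNA rose 6.04-fold and rRNA 1.95-fold, a ratio of 3.09. Neither is the whole cause on these values, a partial contribution of each stays open, and no biological explanation was tested because the design names no difference between the replicates.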
